A study of Pimephales promelas with 40 samples.

How the data were processed

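Liver RNA of adult male fathead minnows (Pimephales promelas, a small North American fish used widely in water quality testing) was measured on 40 Agilent 1-colour arrays, 1 fish per array. Per the labels, fish were held for 12 days in mobile units fed with flowing water, in 2 units of 10 fish per treatment, and livers were drawn at random from the 20 fish. Treatments were treated wastewater effluent and river water downstream of the outfall at the Chisago and North Branch plants in the St. Croix River basin, river water upstream at Chisago, and well water for the Control fish. The labels do not tie a fish to its unit, so p-values measure the spread between fish and an effect of the unit was not tested. The group of each array was taken from its title. The description of North Branch effluent replicate 1 names the Chisago plant while its title, source name and location name North Branch. It was kept as North Branch effluent and left out in an alternative.

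Per the labels' protocols, total RNA was extracted with a column kit, its quality was checked on a Bioanalyzer, and 1 microgram was labelled with Cy3 by linear amplification. Spot intensity values were deposited as scanner output of Agilent Feature Extraction 10.7, per the file headers and the submitters' processing notes. The processed signal in that output is a linear intensity after the background steps of the software, per the file headers. The authors also deposited a value table whose columns, set against the scanner values of the same arrays, are on a log2 scale. Its columns correlated with log2 processed signal at 0.997 or above, and their medians lay between 5.332 and 5.333, with upper quartiles between 8.693 and 8.694 and lower quartiles between 2.919 and 2.921. Nearly equal quantiles in all columns are what quantile normalization gives, a reading taken from the values, since no label or header used here names the method. Direction in this table is that of signal, since higher values went with higher processed signal.

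Each array held 61053 probe spots for 49849 probes of 60 bases, with up to 10 spots per probe. Control spots were left out, as were the 111 to 303 spots per array that the software marked as outliers. Saturated spots numbered 0. Between 57.95% and 77.84% of spots per array were well above background, and the 75th percentile of processed signal ran from 341.2 to 864.8. The number of arrays limits the precision. The log2 of processed signal, computed here from the deposited intensity, was set relative to the array's 75th percentile, and spots of a probe were averaged. Probes well above background on at least 6 of the 40 arrays were kept, which left 39985 probes (80.21%).

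Group means were compared with limma 3.58.1 in R 4.3.3. One model with 6 group means was fitted to all 40 arrays, with 34 residual degrees of freedom, and 11 contrasts were tested two-sided with Benjamini-Hochberg adjustment over the probes kept. A probe was called changed at an adjusted p under 0.05. A moderated F-test asked whether any of the 6 groups differed. The contrasts, groups, model and the settings listed below, apart from those said to be added later, were fixed before the data were examined. A fold against a group in which a probe was not well above background on any array is given as a lower bound. It sets the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the lowest signal among probes well above background and the probe's own signal.

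The array files pair 0 probes with a gene, and no reference sequence was given for this species. The planned tests of gene lists, marker scores of other cell types and list of named genes could therefore not be run. Probes are reported by identifier and sequence. The planned rule for named genes took the largest rises and falls among called probes for which each array of the first group lay on the same side of the second group's mean. It was applied without its condition on gene names, to at most 2 probes a side per comparison, a change made after the files were opened and before any test. Where a named probe is said below to be higher or lower in all fish of a group, this follows from the rule and adds no support. Probes that overlap in sequence were not merged. The 39985 probes tested held 32166 distinct sequences.

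The arrays came from 5 slides of 8 arrays, with 1 scan per slide. Slide was tested as a block. Each slide was also left out in turn, and the direction of the remaining calls was read within it where it held both groups. Other settings were normexp background correction with an offset of 50, quantile normalization, no filter on dim probes, a filter that asked for signal well above background on all 40 arrays, the replicate number as a block, models with only the arrays compared, an intensity trend with robust spread, the deposited value table, array weights, the array with conflicting labels left out and each array left out in turn. After the data were seen, 2 more were added: leaving out 5 arrays that stood apart on the first principal component, by more than 5 scaled median absolute deviations, and the row of the array on its slide as a block.

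The procedure was tested on simulated data built on the 39985 probes, with 200 probes changed in 1 group in each of 5 draws per contrast. More probes were called in the data against Control, and recovery with that many changed probes was not simulated. For Chisago effluent against Control, 27.2% of simulated log2 changes of 1 were recovered, 63.6% of changes of 2, 87.2% of changes of 3 and 96.0% of changes of 4. For North Branch effluent against Control the shares were 19.2%, 66.4%, 85.6% and 95.6%. False calls made up 8.79% and 8.76% of all calls in these simulations, above the nominal level. For North Branch effluent 46 of the 64 false calls came from 1 draw. Comparisons against Control share its arrays. Correlations and overlaps between them were therefore set beside 100 draws of simulated unchanged groups and beside all 35 splits of the Control arrays.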

Results

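Liver transcript levels were measured on 40 arrays from male fathead minnows held for 12 days in well water, in treated wastewater or in river water near a pair of treatment plants. Control, Chisago upstream, Chisago effluent and Chisago downstream had 7 fish each, and North Branch effluent and North Branch downstream had 6 each. The share of spots well above background averaged 69.8% ± 2.82 (SD, n = 7) in Control, 66.0% ± 2.97 (SD, n = 7) in Chisago upstream, 68.3% ± 3.56 (SD, n = 7) in Chisago effluent and 68.8% ± 4.81 (SD, n = 7) in Chisago downstream. It averaged 66.4% ± 4.31 (SD, n = 6) in North Branch effluent and 67.8% ± 5.05 (SD, n = 6) in North Branch downstream. All values below are log2 signal relative to the array's 75th percentile, and all changes are differences of group means.

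The study asked how hepatic transcript levels in field-exposed fish compared with those of fish in well water. Probe SINGLET_6291 (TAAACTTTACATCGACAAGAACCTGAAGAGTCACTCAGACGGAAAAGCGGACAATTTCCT) was higher than in Control in each of the 5 field groups, by 7.84 to 10.55, and by 4.91 to 7.16 with normexp background correction. SINGLET_49235 (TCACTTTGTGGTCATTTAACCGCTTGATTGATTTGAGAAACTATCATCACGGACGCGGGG) was not well above background on any Control array and was measured on 6 of 7 Chisago upstream arrays and on every array of the other 4 field groups. SINGLET_28647 (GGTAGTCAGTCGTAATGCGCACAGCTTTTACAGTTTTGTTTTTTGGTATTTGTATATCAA) was lower in each field group with scaling to the 75th percentile, between -2.83 in Chisago effluent and -5.15 in Chisago upstream, and at -2.13 in the latter with normexp. Where a probe was near background in one group, the size of its difference depended on how that background was treated. The limma F-test called 5528 of 39985 probes, with 11269 at an unadjusted p under 0.05. It called 4876 with slide as a block and 3245 without the 5 arrays that stood apart on the first principal component.

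Against Control, 7921 probes were called in at least 1 field group, and 698 in all 5. Of these 698, 228 were higher in all 5, 468 lower in all 5 and 2 of mixed direction. Median changes of the 228 lay between 1.32 in Chisago downstream and 1.73 in Chisago upstream, and those of the 468 between -1.07 in Chisago downstream and -1.37 in Chisago upstream. Among simulated unchanged groups against the same Control arrays, the highest number called one way in all 5 was 0 in 100 draws. All 5 contrasts had the same sign for 45.5% of the probes tested, where simulated unchanged groups gave a mean of 32.5% and at most 50.7%. Leaving out single arrays moved the 228 to between 167 and 274 and the 468 to between 324 and 544.

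Changes against Control correlated across probes, which are not independent replicates, at 0.40 to 0.783 over the 10 pairs of contrasts, where simulated unchanged groups gave means of 0.472 to 0.509 and highest values of 0.698 to 0.772. In 8 of the 10 pairs the correlation lay below its highest simulated value. With the Control arrays split between the contrasts, the median correlations were 0.017 to 0.41. Covariances were 0.221 to 0.451 against simulated values of 0.128 to 0.144, and the differences were 0.084 to 0.315. The overlap of calls between Chisago upstream and North Branch downstream was 1494 higher and 1257 lower, where independent lists would share 127.3 and 100.1, and with split Control arrays the medians were 453 and 468. For Chisago downstream and North Branch effluent the overlap was 322 higher and 645 lower, against 50.3 and 65.8 for independent lists and 83 and 176 with split Control arrays.

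**Figure D1:**
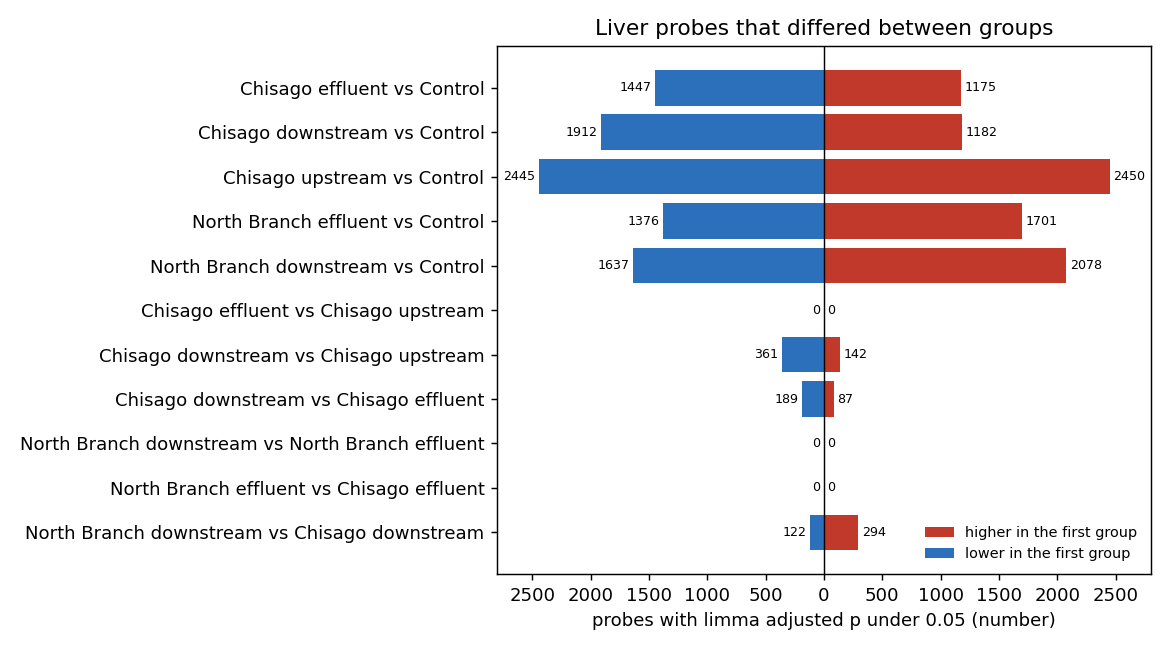
Bars give the number of probes with a limma adjusted p under 0.05 in each of the 11 contrasts, higher in the first group to the right and lower to the left of 0. The 5 contrasts against Control run from 2622 to 4895 probes, and the other 6 from 0 to 503.

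The first principal component held 15.6% of the variance. Arrays of Control replicate 4, Chisago downstream replicates 2, 4 and 5 and Chisago effluent replicate 4 scored 111.6 to 269.4 on it, and the other 35 arrays scored 15.0 or less. By group, the score averaged 77.4 ± 114.7 (SD, n = 7) in Chisago downstream and -31.7 ± 16.2 (SD, n = 7) in Chisago upstream, with a two-sided exact permutation p of 0.0146 and an adjusted p of 0.147 over 11 contrasts. Against Control, which averaged 20.6 ± 110.1 (SD, n = 7), Chisago downstream had an exact permutation p of 0.452.

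**Figure D2:**
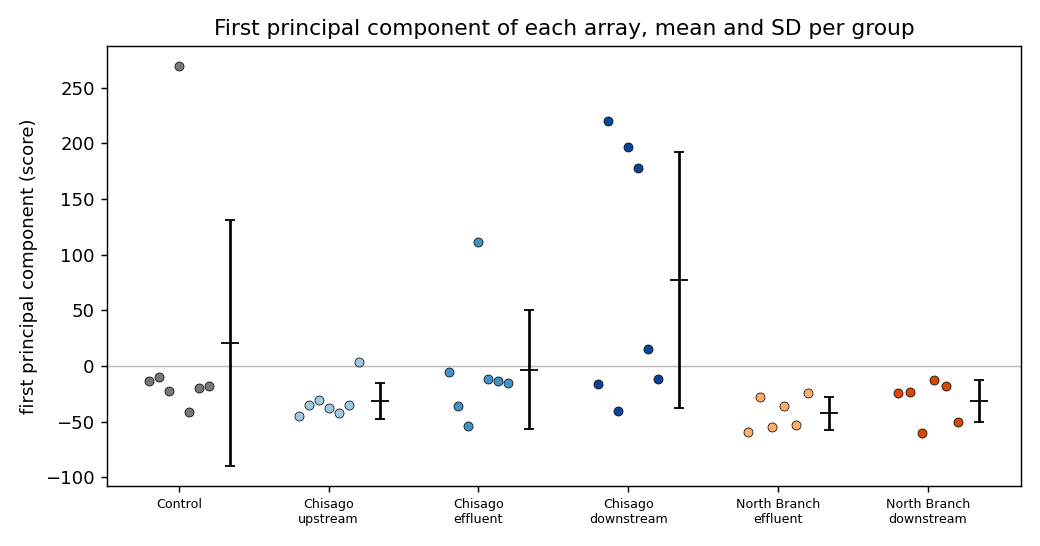
Each point is the score of 1 array on the first principal component, by group, with the group mean and SD beside the points. The 5 arrays from 111.6 to 269.4 are Control replicate 4, Chisago downstream replicates 2, 4 and 5 and Chisago effluent replicate 4, and the other 35 lie at 15.0 or below.

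Chisago effluent against Control asked which transcripts differed in fish held in effluent. SINGLET_6291 stood at 2.49 ± 1.23 (SD, n = 7) in effluent fish and at -6.34 ± 1.90 (SD, n = 7) in Control, where 2 of 7 arrays were well above background, a difference of 8.83 with limma adjusted p = 1.6e-05, higher in 7 of 7 fish. UF_Ppr_AF_114701 (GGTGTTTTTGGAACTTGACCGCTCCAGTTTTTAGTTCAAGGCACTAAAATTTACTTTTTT) was higher by 7.91, with limma adjusted p = 0.007, and varied widely in Control at -2.79 ± 5.36 (SD, n = 7). CONTIG1138 was lower, at -4.23 ± 1.90 (SD, n = 7) against -0.64 ± 0.98 (SD, n = 7), with limma adjusted p = 0.0032, and was well above background in 4 of 7 effluent fish. SINGLET_5798 was not well above background on any effluent array and was at least 13.9-fold lower than in Control, with limma adjusted p = 0.023. With normexp the differences were 5.51 for SINGLET_6291, -1.93 for CONTIG1138 and -1.79 for SINGLET_5798, the last smaller than its bound. Across all probes limma called 2622, 1175 higher and 1447 lower, from 2096 distinct sequences, and 1520 differed at least 2-fold. With slide as a block 2680 were called, and within single slides 73.7% to 96.6% of the calls made without that slide kept their direction. With only the arrays of these groups 1259 were called, and the call of SINGLET_5798 was lost there (adjusted p = 0.071), with normexp (0.14), and without Control replicate 5 or 6 (adjusted p up to 0.075), all by limma.

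Chisago downstream against Control concerned river water below the outfall. SINGLET_6291 was higher by 9.03, at 2.69 ± 2.97 (SD, n = 7), with limma adjusted p = 1.2e-05. SINGLET_49235 was at least 67.5-fold higher than in Control, with limma adjusted p = 0.00068. With normexp the differences of these probes were 5.75 and 3.05, the second smaller than its bound. SINGLET_31884 (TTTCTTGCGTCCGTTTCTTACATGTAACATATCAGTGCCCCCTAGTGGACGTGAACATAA) was lower in 7 of 7 fish, at -3.46 ± 1.48 (SD, n = 7) against 3.10 ± 1.74 (SD, n = 7), with limma adjusted p = 6.7e-05. UF_Ppr_AF_103721, whose sequence overlaps that of SINGLET_31884, differed by -6.35, with limma adjusted p = 9.2e-05. Limma called 3094 probes, 1182 higher and 1912 lower, from 2480 distinct sequences, and 1829 differed at least 2-fold. The slide block gave 2885 calls, and within single slides 66.5% to 96.6% of calls kept their direction. The count was 5058 without Control replicate 4, 1998 without the 5 arrays high on the first principal component and 1161 with only the arrays of these groups.

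Chisago upstream against Control concerned river water above the outfall. SINGLET_11655 (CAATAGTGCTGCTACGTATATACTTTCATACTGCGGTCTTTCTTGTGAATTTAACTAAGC) was higher in 7 of 7 fish, at -0.22 ± 1.2 (SD, n = 7) against -6.90 ± 1.81 (SD, n = 7), with limma adjusted p = 1.2e-05, and was well above background in 1 of 7 Control fish. SINGLET_6291 was higher by 7.84, with limma adjusted p = 1.6e-05, and was well above background in 6 of 7 fish. SINGLET_28647 was lower, at -5.86 ± 1.34 (SD, n = 7) against -0.71 ± 1.03 (SD, n = 7), with limma adjusted p = 7.9e-06, and UF_Ppr_AF_116501 differed by -5.13, with limma adjusted p = 0.0013. Both were well above background in 2 of 7 upstream fish. With normexp the 4 differences were 3.04, 4.91, -2.13 and -2.19 in the order named. Limma called 4895 probes, 2450 higher and 2445 lower, from 3927 distinct sequences, and 2816 differed at least 2-fold. Blocking by slide gave 4874 calls, and within the 4 slides that held both groups 83.9% to 93.3% of calls kept their direction. With normexp 7451 were called, 70.7% of them higher against 50.05%, and with only the arrays of these groups 2979 were called, 45.5% of them higher. The share was 44.9% with quantile normalization.

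North Branch effluent against Control asked the same question at the other plant. SINGLET_6291 was higher by 8.49, at 2.15 ± 1.43 (SD, n = 6), with limma adjusted p = 3.3e-05, and SINGLET_49235 was at least 70.1-fold higher, with limma adjusted p = 0.00078. With normexp these differences were 5.14 and 2.90, the second smaller than its bound. CONTIG6065 was lower in 6 of 6 fish, at -1.47 ± 0.74 (SD, n = 6) against 2.97 ± 1.54 (SD, n = 7), with limma adjusted p = 0.0016. UF_Ppr_AF_109101 was lower, at -5.50 ± 1.2 (SD, n = 6) against 0.50 ± 3.69 (SD, n = 7), with limma adjusted p = 0.027 and a difference of -3.79 with normexp. Limma called 3077 probes, 1701 higher and 1376 lower, from 2465 distinct sequences, and 1938 differed at least 2-fold. The 55.3% that were higher became 47.6% with quantile normalization, 47.7% with the deposited value table, 47.0% with only the arrays of these groups and 49.6% without the 5 arrays high on the first principal component. With slide as a block 3062 were called, and within single slides 79.2% to 95.7% of calls kept their direction. Of the effluent arrays 1 lay in row 1 of its slide and 5 in row 2, against 5 and 2 of the Control arrays. Slide row as a block gave 2242 calls. With only the arrays of these groups 1509 were called, and 2187 without replicate 1, whose labels conflict. The call of UF_Ppr_AF_109101 was lost without the 5 arrays high on the first principal component (limma adjusted p = 0.057), with slide row as a block (0.065), and without North Branch effluent replicate 2 or 5 or Control replicate 2, 4, 5 or 7, where it reached 0.062.

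North Branch downstream against Control concerned river water below that outfall. SINGLET_6291 was higher by 10.55, at 4.21 ± 1.73 (SD, n = 6), with limma adjusted p = 6.4e-06, or by 7.16 with normexp, and UF_Ppr_AF_114701 was higher by 8.62, at 5.83 ± 0.83 (SD, n = 6), with limma adjusted p = 0.0034. SINGLET_46293 was lower in 6 of 6 fish, at -1.81 ± 3.84 (SD, n = 6) against 4.24 ± 0.91 (SD, n = 7), with limma adjusted p = 0.0014. UF_Ppr_AF_115084 was lower, at -4.18 ± 1.41 (SD, n = 6) against 0.63 ± 1.62 (SD, n = 7), with limma adjusted p = 0.009, and was well above background in 4 of 6 downstream fish. Limma called 3715 probes, 2078 higher and 1637 lower, from 2974 distinct sequences, and 2338 differed at least 2-fold. The slide block gave 3804 calls, and within single slides 78.0% to 93.5% of calls kept their direction. With only the arrays of these groups 1125 were called. Slide row as a block gave 2934, where 2 downstream arrays lay in row 1 and 4 in row 2.

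Chisago effluent against Chisago upstream set the effluent beside the river it enters. SINGLET_6291 differed by 0.99 with an SE of 1.16 and limma adjusted p = 0.95, and SINGLET_49235 stood at -1.42 ± 2.31 (SD, n = 7) in effluent fish and -1.07 ± 3.40 (SD, n = 7) in upstream fish. Limma called 0 probes, with 2193 at an unadjusted p under 0.05 where 1999 would arise by chance. The 95% interval of the difference excluded a 2-fold change for 45.0% of probes. Blocking by slide gave 0 calls, array weights gave 2, and 2 were also called without Chisago upstream replicate 5. With slides left out in turn, 0 to 4 were called, too few for values within a slide.

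Chisago downstream against Chisago upstream set water below the outfall beside water above it. SINGLET_3504 (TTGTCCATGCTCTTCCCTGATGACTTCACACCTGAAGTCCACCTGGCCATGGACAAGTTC) was higher in 7 of 7 downstream fish, at 1.57 ± 1.36 (SD, n = 7) against -3.13 ± 1.07 (SD, n = 7), with limma adjusted p = 0.0048. UF_Ppr_AF_107837 was higher by 4.43, with limma adjusted p = 0.031. SINGLET_11655 was lower, at -5.01 ± 1.79 (SD, n = 7) against -0.22 ± 1.2 (SD, n = 7), with limma adjusted p = 0.014 and a difference of -2.51 with normexp, and UF_Ppr_AF_100639 stood at -2.26 ± 1.83 (SD, n = 7) against 2.25 ± 1.26 (SD, n = 7), with limma adjusted p = 0.0049. Limma called 503 probes, 142 higher and 361 lower, from 429 distinct sequences. Among them UF_Ppr_AF_118252 and CONTIG7533, named between the downstream groups below, differed by less but with smaller p. They were lower downstream, at -3.68 and -3.79, each with limma adjusted p = 7.7e-07. How these 2 differences depend on the setting was not examined here.

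This count depended on single fish and on the setting. It was 85, 1689, 54, 87, 222 and 887 without Chisago downstream replicates 2, 3, 4, 5, 6 and 7 in that order, and 313, 191, 312, 254, 196 and 201 without Chisago upstream replicates 1 to 6. Without Control replicate 4 it was 1386. With slide as a block 97 were called. Within slides 1, 2 and 4 the direction held for 93.3%, 97.2% and 100% of the 15, 71 and 14 calls made without the slide, and within slide 3, which held Chisago downstream replicate 3, for 66.7% of 438. Slide 5 held no upstream array. Without the 5 arrays high on the first principal component 14 were called, and the calls of UF_Ppr_AF_107837, SINGLET_11655 and UF_Ppr_AF_100639 were lost (limma adjusted p = 0.33, 0.078 and 0.066), with differences of 2.35, -5.15 and -3.91. The call of UF_Ppr_AF_107837 was also lost with slide as a block (limma adjusted p = 0.11), with only the arrays of these groups (0.089), and without Chisago downstream replicate 2, 4 or 5 or Chisago upstream replicate 2, 4 or 5, where it reached 0.095. The count was 294 with no filter on dim probes, 999 with only probes well above background on all 40 arrays and 900 with the replicate block. It was 1368 with array weights and 38 with only the arrays of these groups.

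Chisago downstream against Chisago effluent set water below the outfall beside the effluent itself. SINGLET_3504 was higher by 4.39, with limma adjusted p = 0.0095, against -2.83 ± 2.01 (SD, n = 7) in effluent fish. UF_Ppr_AF_101004 was higher, at -3.12 ± 0.27 (SD, n = 7) against -6.22 ± 1.98 (SD, n = 7), with limma adjusted p = 0.046, and was well above background in 2 of 7 effluent fish. SINGLET_31884 was lower by a difference of -5.32, with limma adjusted p = 0.008, and the overlapping UF_Ppr_AF_103721 by one of -5.06, with limma adjusted p = 0.01. Limma called 276 probes, 87 higher and 189 lower, from 228 distinct sequences. Among them UF_Ppr_AF_118252 and CONTIG7533 were lower downstream, at -3.07 and -3.20, with limma adjusted p = 6.7e-05 and 6.1e-05. How these 2 differences depend on the setting was not examined here either.

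The slide block gave 242 calls. Within slides 1 and 3 the direction held for 54.8% and 65.4% of the 341 and 312 calls made without the slide, and slides 2, 4 and 5 rested on 4, 9 and 3 calls. The count was 47, 858, 53, 68, 137 and 142 without Chisago downstream replicates 2 to 7, 57, 113, 55, 70 and 93 without Chisago effluent replicates 1, 2, 3, 5 and 7, and 566 without Control replicate 4. It was 6 without the 5 arrays high on the first principal component, where the calls of SINGLET_31884, UF_Ppr_AF_103721 and UF_Ppr_AF_101004 were lost (limma adjusted p = 0.18, 0.22 and 0.31), with differences of -4.85, -4.49 and 2.88. With only the arrays of these groups 15 were called, and SINGLET_3504 lost its call (limma adjusted p = 0.073). UF_Ppr_AF_101004 lost its call with 19 of the 40 arrays left out singly, with limma adjusted p up to 0.11, and in 7 other settings, where its difference was 0.66 with normexp and 2.88 to 3.13 in the rest. The count was 150 with no filter on dim probes, 548 with only probes well above background on all 40 arrays and 486 with the replicate block. It was 549 with array weights and 182 with slide row as a block.

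North Branch downstream against North Branch effluent made the same comparison at the second plant. SINGLET_6291 differed by 2.07 with an SE of 1.25 and limma adjusted p = 0.69. SINGLET_31884 stood at -0.22 ± 1.34 (SD, n = 6) downstream and 3.24 ± 1.24 (SD, n = 6) in effluent, and was not called. Limma called 0 probes, with 3389 at an unadjusted p under 0.05 where 1999 would arise by chance, and the 95% interval excluded a 2-fold change for 37.5% of probes. With slide as a block, and with any slide left out, 0 were called. The count was 20 with only probes well above background on all 40 arrays, 4 with only the arrays of these groups, 19 without North Branch downstream replicate 5, and 3 and 2 without North Branch effluent replicates 4 and 6.

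North Branch effluent against Chisago effluent tested whether the effluents differed in effect, since Control cancels from the difference. SINGLET_6291 differed by -0.34 with an SE of 1.21 and limma adjusted p = 0.98. CONTIG6065 stood at -1.47 ± 0.74 (SD, n = 6) in North Branch and -0.43 ± 1.43 (SD, n = 7) in Chisago effluent. Limma called 0 probes, with 2097 at an unadjusted p under 0.05 where 1999 would arise by chance, and 0 in each alternative. The 95% interval excluded a 2-fold change for 42.4% of probes, so smaller changes and those of the other probes were not excluded.

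North Branch downstream against Chisago downstream tested whether the downstream waters differed in effect. UF_Ppr_AF_118252 and CONTIG7533, which share the sequence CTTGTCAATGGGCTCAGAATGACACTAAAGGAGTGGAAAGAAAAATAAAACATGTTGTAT, were higher by 4.31 and 4.27, each with limma adjusted p = 5.2e-08. UF_Ppr_AF_118252 stood at 4.22 ± 0.72 (SD, n = 6) in North Branch and -0.08 ± 0.70 (SD, n = 7) in Chisago fish. Against Control, this probe was higher in Chisago effluent, Chisago upstream, North Branch effluent and North Branch downstream, by 1.58, 2.19, 2.33 and 2.82, and lower in Chisago downstream, at -1.49, with limma adjusted p = 0.016 for the last. SINGLET_3504 was lower in North Branch fish, at -4.11 ± 0.82 (SD, n = 6) against 1.57 ± 1.36 (SD, n = 7), with limma adjusted p = 0.00099. SINGLET_41387 was not well above background on any North Branch downstream array and was at least 4.71-fold lower, with limma adjusted p = 0.045. Limma called 416 probes, 294 higher and 122 lower, from 350 distinct sequences.

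Blocking by slide gave 237 calls. Within slides 1, 2, 4 and 5 the direction held for 75.9%, 88.2%, 97.4% and 91.0% of the 54, 135, 39 and 67 calls made without the slide, and within slide 3, which held Chisago downstream replicate 3, for 46.9% of 456. The count was 115, 1078, 87, 102 and 838 without Chisago downstream replicates 2, 3, 4, 5 and 7, 122 and 225 without North Branch downstream replicates 3 and 4, and 877 without Control replicate 4. It was 22 without the 5 arrays high on the first principal component, 741 with only probes well above background on all 40 arrays, 779 with the replicate block and 12 with only the arrays of these groups. The 70.7% that were higher became 45.5% and 41.7% in the first and last of these settings. SINGLET_41387 lost its call in 8 other settings and with 17 of the 40 arrays left out singly, with limma adjusted p up to 0.38, and its difference was -0.85 with normexp, smaller than its bound. UF_Ppr_AF_118252 stayed between 4.13 and 4.54 with any single array left out.

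**Figure D3:**
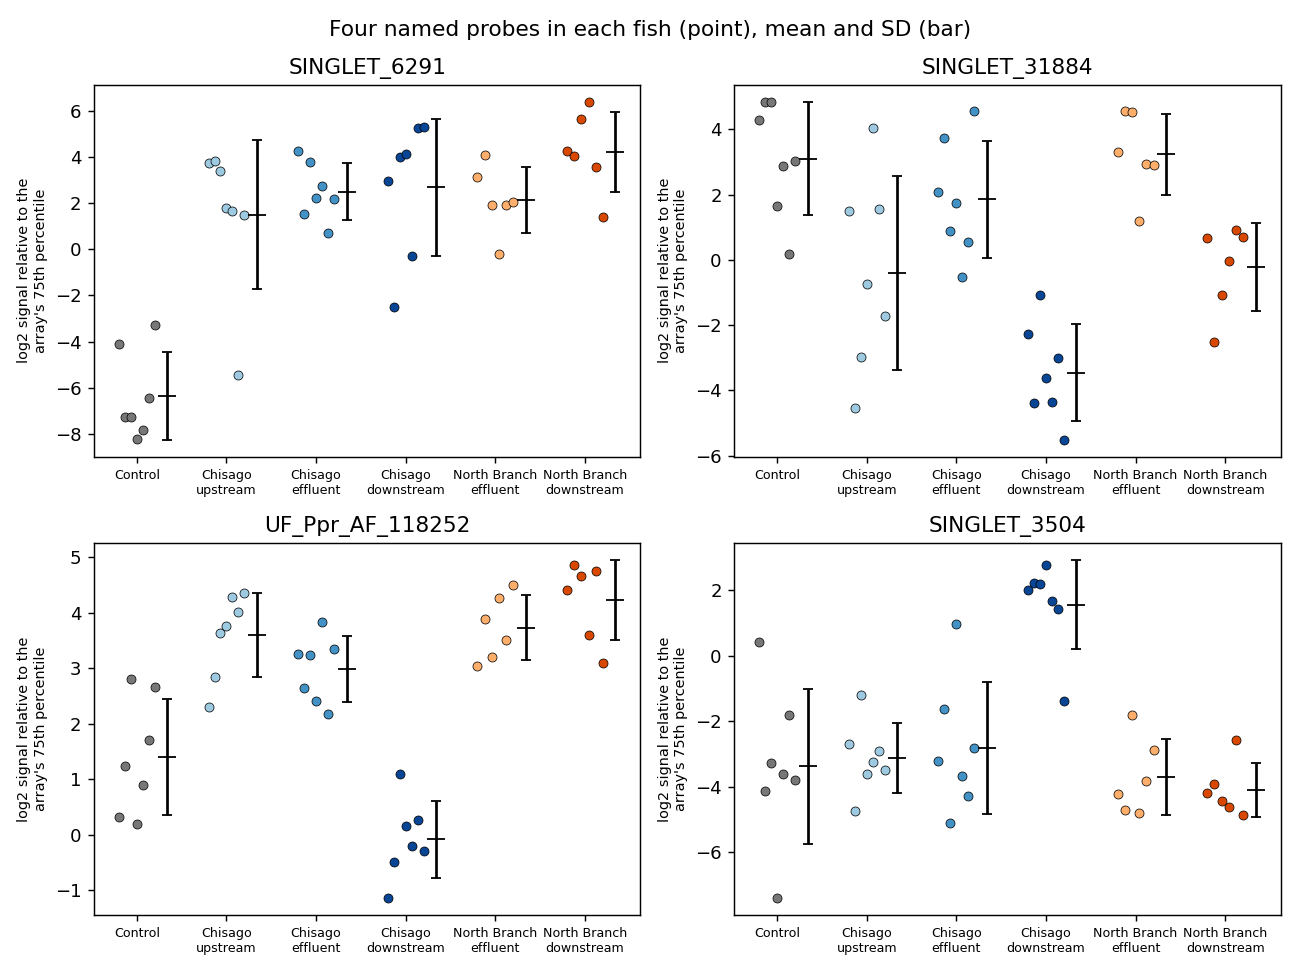
Each point is 1 fish, by group, with the group mean and SD beside the points, and the axis is log2 signal relative to the array's 75th percentile for SINGLET_6291, SINGLET_31884, UF_Ppr_AF_118252 and SINGLET_3504. SINGLET_6291 averages -6.34 in Control and 1.5 to 4.21 in the field groups, and UF_Ppr_AF_118252 averages -0.08 in Chisago downstream and 1.40 to 4.22 elsewhere.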

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

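The tests on the 5 arrays high on the first principal component, here and in the weighing of the shared difference from Control, were chosen after that component was seen. For Chisago downstream, the tests with slide as a block and the separate reading of slide for each comparison were chosen after their results were seen, and the reading of the test that left out 3 fish was made stricter after its value was seen.

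Single fish stood far from the rest of their group in 11 of 126 cases, all 6 groups for each named probe (8.73%). For independent, normally distributed values chance would give about 1 in 20. The named probes were picked for large differences, came from the same arrays and partly share sequence, so an excess over chance is not shown. UF_Ppr_AF_114701 was at 1.30 in Chisago effluent replicate 3, -3.85 in Chisago upstream replicate 7 and -4.97 in Chisago downstream replicate 5, with the nearest fish of the group at 4.59, 5.52 and 4.74. Chisago downstream replicate 6 was at 3.0 for SINGLET_5798 and replicate 7 at -1.37 for SINGLET_3504, with the nearest at -5.48 and 1.43. CONTIG1138 was at -2.75 in Control replicate 2 and SINGLET_41387 at -2.63 in Control replicate 4, with the nearest at -0.62 and -7.34. In Chisago upstream, SINGLET_6291 was at -5.43 in replicate 6 and SINGLET_46293 at 2.71 in replicate 5, with the nearest at 1.5 and -0.82. CONTIG6065 was at 4.25 in North Branch downstream replicate 6 and UF_Ppr_AF_107837 at 5.54 in Chisago effluent replicate 4, with the nearest at -0.35 and 1.03.

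The downstream groups of the plants differed in a direct test, with 416 probes called by limma, 22 without the 5 arrays high on the first principal component and 12 with only the arrays of these groups. UF_Ppr_AF_118252 and CONTIG7533 differed by 4.31 and 4.27, SINGLET_3504 by -5.67 and SINGLET_41387 by -3.29. The size of the last is uncertain, since SINGLET_41387 was not well above background on any North Branch downstream array. As a lower bound it was at least 4.71-fold lower there, and with normexp its difference was -0.85, smaller than that bound. The call of SINGLET_41387 was lost in several settings named in the report.

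Other splits of the same arrays were counted, 100 per comparison with the real one included. They regrouped single fish, so they cannot exclude chance differences between exposure units. Chance in how fish fell into groups was argued against for Chisago effluent, downstream and upstream against Control. There 1 split, the real one, called as many probes: 2622, 3094 and 4895 against at most 601, 1239 and 1383 in the others. It was also argued against for North Branch effluent and downstream against Control, with 3077 and 3715 against at most 610 and 2419. For the F-test it was as well, with 5528 against at most 13. The same held for Chisago downstream against Chisago effluent, with 276 against at most 3, and for North Branch against Chisago downstream, with 416 against at most 93. For Chisago downstream against Chisago upstream 2 splits called as many, with 503 in the real one and at most 649 in the others. Chance was argued against there but not excluded, since another split called more probes than the real one. For the 3 comparisons in which limma called 0 probes, all 100 splits necessarily called as many, with at most 3, 6 and 62 in the others, so the count of splits decides nothing there. Unadjusted p under 0.05 was reached there by 2193, 3389 and 2097 probes.

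A set of 1422 probes lay more than 3 log2 above the other arrays' median in Control replicate 4, and its median excess was 3.39, 3.22 and 3.08 in Chisago downstream replicates 2, 4 and 5 and 2.54 in Chisago effluent replicate 4, while in each of the other 35 arrays it lay between -0.51 and 0.87. Array brightness as the whole cause was argued against, since 6 other arrays were as bright as the dimmest of these 5 and stayed low. A part played by brightness stays open, as the 5 had 75th percentiles of signal of 541.7 to 864.8, and 864.8 was the highest of all arrays. Slide as the whole cause was argued against, since most arrays on the 3 slides of these 5 stayed low. The share that stood apart there, 20.8%, was fixed once 5 arrays lay on 3 slides. A part played by slide stays open, as the other slides held none of the 5. The highest of the other arrays, Chisago downstream replicate 6 at 0.87, lay on slide 5 with Chisago downstream replicate 5 and Chisago effluent replicate 4. The excess over these probes correlated at 0.754 to 0.83 between the 4 arrays not used to pick them, so one source of RNA or one state shared by the fish may lie behind it, and these cannot be told apart without gene names. An effect of exposure stays open, as Chisago downstream against Control gave an exact permutation p of 0.452 and a Control fish is among the 5. The set held 1.52% of the calls for Chisago downstream against Control and 4.57% of those against Chisago upstream, with 3.56% of all probes tested. It held 0.36% of the calls for Chisago downstream against Chisago effluent and 0.48% of those for North Branch against Chisago downstream.

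The field groups shared a difference from Control, with 696 probes called one way in all 5 contrasts. Slide was argued against, as a median of 87.1% of calls (lowest 66.5%) kept their direction within a slide left out, and so was brightness as the whole cause, as at least 64.5% of calls stayed with it as a covariate. Chance values of the Control arrays as the whole cause were argued against by 0 of 100 simulated draws with as many. Those draws held no changed probe, so they cannot show how far shared Control values added to the 696. A part played by these values stays open, as 8 of the 10 correlations between contrasts lay below their highest simulated value. The 5 arrays high on the first component were argued against by the 69.8% of the 696 probes that stayed called without them. With slide row as a block 196 of the 228 higher and 383 of the 468 lower probes stayed called in all 5. A part played by row stays open, as rows were unevenly spread over Control and the North Branch groups. What also stays open, untested, is the exposure unit, anything else in which the Control units differed from those in the field, and the difference between well water and river or effluent water itself. A shared response to field water may therefore be proposed only as a hypothesis.

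Chisago downstream differed from Chisago upstream, Chisago effluent and North Branch downstream, by 503, 276 and 416 probes. Slide as the whole cause was argued against, as with slide as a block the median changes went from 1.23 (SE 0.29) to 1.19 (SE 0.31), from 1.27 (SE 0.28) to 1.27 (SE 0.28) and from 1.17 (SE 0.27) to 1.13 (SE 0.27), 78.6% of the calls against Chisago effluent and 53.6% of those against North Branch downstream stayed, and within slides at least 66.7% of calls against Chisago upstream kept their direction. A part played by slide stays open, as 18.1% of the 503 stayed called with the block, where the error widened, and the median within-slide share of 89.6% gives slides with few calls equal weight: the share was 54.8% of 341 and 65.4% of 312 calls in slides 1 and 3 against Chisago effluent and 46.9% of 456 in slide 3 against North Branch downstream, and pooled over slides it was 72.3%, 60.7% and 63.0%. That replicates 2, 4 and 5 carried the difference stays open: leaving out 3 fish but none of these gave 1838 to 4800, 55 to 2832 and 1927 to 4321 calls and leaving out these 3 gave 6, 6 and 10, as few as in 7, 12 and 3 of the 35 ways, of which 6, 6 and 3 left out at least 2 of them, while median changes without them were 0.98, 1.05 and 0.96, with 100% in the same direction, over probes chosen with all 7 fish. With brightness as a covariate 42.7% of the 503 calls stayed and 100% of the 276 and of the 416, and an effect of the water, of its exposure units or of single fish may each contribute.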

How the results depend on the processing

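Leaving out the 5 arrays high on the first principal component and using slide row as a block were chosen after seeing the data, and the other settings were planned. No count and no named probe reversed. Among all probes called at first, the sign turned with normexp for 117 of 4895 in Chisago upstream against Control and for 1 to 12 in 5 other contrasts, and with the deposited value table for 1 in North Branch effluent against Control. The share of higher probes turned to a minority in settings given in the report for North Branch effluent against Control and between the downstream groups, and for Chisago upstream against Control, at 50.05%, also with the deposited value table (44.9%), with array weights (47.6%), with slide row as a block (48.4%), without the array with conflicting labels (49.8%) and without the 5 arrays (46.1%). The 32 differences of named probes kept direction and call in 364 cases over the settings other than single arrays left out, and lost the call in 27, covered in the report. The cause of a moved count was not tested unless a reason is given. Dim signal limits the probes near background: folds are bounds only where no array of a group was well above it, and with normexp, which adds an offset, the other differences of such probes shrank as well, to as little as 0.66.

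Normexp gave 7451 probes for Chisago upstream against Control (70.7% higher against 50.05%), where the median of all probes moved from 0.083 to 0.259. It moved from 0.009 to 0.112 for Chisago downstream and from 0.066 to 0.173 for North Branch effluent with normexp, and from 0.123 to 0.008 for Chisago effluent with quantile normalization. With no filter, more probes entered the adjustment and Chisago downstream gave 294 against upstream and 150 against effluent. With probes well above background on all 40 arrays, fewer entered and the counts were 999 and 548, with 20 for North Branch downstream against effluent and 741 for North Branch against Chisago downstream. Slide as a block gave 97 for Chisago downstream against upstream and 237 between the downstream groups. Array weights gave 2 for Chisago effluent against upstream, and 1368 and 549 for Chisago downstream against upstream and effluent. Slide row as a block gave 182 for the last.

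With only the arrays of the groups compared, fewer residual degrees of freedom were left. Counts against Control were 1259 and 1509 for Chisago and North Branch effluent, 1161 and 1125 for downstream and 2979 for upstream. Chisago downstream gave 38 against upstream and 15 against effluent, and North Branch downstream gave 4 against effluent and 12 against Chisago downstream. Without the 5 arrays, mostly from Chisago downstream, this group gave 1998 against Control, 14 against upstream, 6 against effluent and 22 against North Branch downstream, and the F-test 3245. How far a smaller number of fish accounts for these drops is not settled. Leaving out 3 Chisago downstream fish other than replicates 2, 4 and 5 together also lowered the counts. Their medians were then 82.5 against upstream, 20 against effluent and 117.5 against North Branch downstream. Leaving out 3 but none of these replicates gave 1838 to 4800, 55 to 2832 and 1927 to 4321 in that order. These replicates were then most of the fish left, so number and choice of fish cannot be told apart. Without the 5 arrays 213 probes were higher and 377 lower in all 5 contrasts against Control, 155 and 331 of them among the original 228 and 468.

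With single arrays left out, counts against Control were 1835 to 2872 and 2187 to 3245 for Chisago and North Branch effluent, 2190 to 5058 and 2559 to 4281 for downstream and 3905 to 5027 for upstream. Chisago effluent against upstream gave 0 to 2 by limma, against 2193 at an unadjusted p under 0.05. Chisago downstream gave 54 to 1689 against upstream and 47 to 858 against effluent. North Branch downstream gave 0 to 19 against effluent by limma, against 3389 at an unadjusted p under 0.05, and 87 to 1078 against Chisago downstream. The F-test gave 4477 to 6313. The arrays behind moves of over 1.5 times are named in the report.

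The replicate block gave 900 for Chisago downstream against upstream, 486 against effluent and 779 for North Branch against Chisago downstream, and moved no other count by over 1.5 times. Each other count above 0 rose as well, as from 3715 to 4059 for North Branch downstream against Control. Whether the replicate numbers pair the arrays was left undecided. Over 96 pairs with the same number the median correlation of deviations was 0.004, against -0.006 over 570 other pairs. Of the 96 pairs, 18 exceeded 0.1, and 12 of 40 arrays correlated best with their own number. No chance level was computed for these counts, so a pairing is not excluded.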

Other observations

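The score of field fish beside Control fish was chosen after a form of it that favoured the field fish had been seen, and the reading of the opposite-strand pairs was changed after its result to use upper bounds of the correlation. The other test was set before its result was seen.

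Each of the 33 field arrays was left out together with 1 Control array, 3 times with different Control arrays. Both were scored with the probes called one way in all 5 contrasts against Control without them. The score was the mean difference from the other Control arrays over higher probes minus that over lower probes, divided by 2. Control fish scored 0.24 ± 0.25 (SD, n = 7), and the field groups 1.76 ± 0.20 (SD, n = 7) in Chisago upstream, 1.53 ± 0.27 (SD, n = 7) in Chisago effluent, 1.41 ± 0.30 (SD, n = 7) in Chisago downstream, 1.61 ± 0.17 (SD, n = 6) in North Branch effluent and 1.61 ± 0.35 (SD, n = 6) in North Branch downstream. The field fish scored above the Control fish left out with it in 99 of 99 pairs, by at least 0.53, which argues against a difference carried by single fish of each group. The exposure unit stays open here as well.

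Probes with at least 30 bases in common on the same strand formed 8294 pairs, of which 4409 were identical. Their changes against Control correlated across pairs at 0.917 or above in all 5 contrasts, where random pairs of probes gave -0.008 to 0.009, which is consistent with probes of one transcript reporting one change. Pairs are not independent replicates. On opposite strands there were 16 such pairs, with correlations of -0.391 to 0.385 over the 5 contrasts. The upper 95% bound of the lowest, adjusted for 5 contrasts, was 0.293 and that of the highest 0.808. A change measured alike on both strands in every contrast was thus argued against, but only weakly. The pairs held 29 probes, so some shared a probe and the bounds are too narrow, and 0 pairs had both probes called in any contrast.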
